A study of Mus musculus with 6 samples.

How the data were processed

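RIP-seq libraries from mouse E14 embryonic stem cells of the Tip60-H3F genotype were made with IgG, an antibody against Ruvbl1 or an antibody against p400, in 2 libraries each. The deposited values were RPKM in both tables, which the authors computed before deposit, reads scaled to the length of the gene span and to the library total, with 1 column per library and no pooling. One table listed RefSeq genes (31645 entries) and the other noncoding transcripts (5894 entries, 5669 with Ensembl transcript identifiers and 225 with lincRNA names). The tools CASAVA 1.8.2, TopHat2 and HOMER and the build mm9 are named per the submitters' processing notes, and their roles are not given. The gene annotation, the treatment of duplicate and multiply mapped reads, and the strand setting of the counting are not given in the sources used here.

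Library totals and read numbers were recovered from the deposited RPKM. In each library the product of RPKM and gene span (introns included) was a whole multiple of a fixed step, within 0.02 of a read for 99.8 to 99.9% of RefSeq values and for 100% of noncoding values. The steps gave library totals between 99849 and 7722302 reads. IgG replicate 1 had a total of 588724 in the RefSeq table and 290700 in the noncoding table, with equal read numbers at each of the 102 loci above 0 in both. Gene spans in the RefSeq table held 24.2% of the total of IgG replicate 1 and 39.9 to 42.8% of the other totals after 1 entry per symbol was kept. In the noncoding table, with its smaller total, IgG replicate 1 held 4.64% and the others 4.46 to 8.67%. Its share thus stood apart in the RefSeq table and not in the noncoding table, which are shares of different spans. It had 142536 reads in RefSeq gene spans, so with the smaller total its share there would lie above the others. The shares therefore do not settle which total is right, and the sources do not say. Entries at 0 made up 28.5 to 75.2% of the RefSeq table and 42.4 to 87.8% of the noncoding table. The counting gives whole gene spans, so reads of a small RNA inside an intron also count for its host gene, and reads of overlapping genes cannot be told apart.

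For the RefSeq table, the entry with the highest mean RPKM was kept per symbol (23952 symbols), while the noncoding table was kept entry by entry. Noncoding transcripts took gene symbols from GENCODE vM21 (GRCm38) by identifier, which named 4565 of 5669 (80.5%), and no coordinates of that build were used. Entries with a mean RPKM of at least 0.5 over the 6 libraries were tested, 5022 genes and 933 noncoding entries. Values were log2(RPKM + 1), so fold changes understate those of low genes. They were fitted with limma 3.58.1 in R 4.3.3, all 6 libraries of a table in one fit with group as the only term, 3 residual degrees of freedom, moderated variances without a trend, two-sided tests and Benjamini-Hochberg adjustment with a threshold of 0.05. This was the design written for RPKM values. Comparisons were p400 against IgG, Ruvbl1 against IgG and p400 against Ruvbl1.

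A fold against a group without reads was computed against 3 reads over the group's libraries together, and ratios of few reads have exact 95% counting intervals. Differences in all 4 library pairs were counted, for which exchangeable libraries would give 16.7% in each direction. Libraries of such unequal depth are not exchangeable, so these shares test nothing. Of 21 gene lists, the 16 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists were Tip60-p400 complex subunits, pluripotency factors, germ-layer and lineage regulators, fibroblast (feeder) markers, primitive endoderm markers, cytoplasmic ribosomal proteins, replication-dependent histones, mitochondrially encoded genes, oxidative phosphorylation subunits, spliceosome and SR proteins, chromatin enzymes, cell cycle and replication genes, immediate-early and stress genes, snoRNAs, their box C/D and H/ACA classes, snoRNA host genes, small nuclear RNAs, microRNA precursors, nuclear-retained and imprinted long noncoding RNAs, and antisense transcripts.

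Genes named in the text followed a fixed rule. Per comparison and table, it took the genes past the threshold and changed the same way in all 4 library pairs, up to the 10 largest fold changes upward and 5 downward (8 and 4 in the noncoding table). Where fewer passed, it took genes by unadjusted p with the 4 pairs in 1 direction, up to 5 per direction, said not to pass. Up to 4 measured members of each list with the smallest unadjusted p were added, and Ruvbl1, Ep400, Kat5, Malat1, Neat1, Xist, Kcnq1ot1, Rn7sk, Terc, Rmrp and Rpph1 wherever listed. Abundant genes at 0, Tsix, Snord22 and the genes of replicate 2 were named after their values were seen. The comparisons, the naming rule, the gene lists and the main alternative settings were fixed before the data were examined.

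The statistics were first tested on simulated data. Reads were drawn at the real library totals and gene means with extra spread taken from the Ruvbl1 and p400 replicates, in 20 draws with 100 genes changed 4-fold and 100 changed 16-fold. Gene means were mean RPKM over all libraries, not weighted by depth. A single read of IgG replicate 2 on a short entry could thus set a high level for every library. Simulated rises of short entries over IgG can therefore be too large. For p400 against IgG, 15.5% of 4-fold and 88.0% of 16-fold changes were recovered over 5022 genes, for Ruvbl1 against IgG 15.9% and 88.9%, and for p400 against Ruvbl1 9.80% and 82.9%. Unchanged genes called beside them were a mean of 24.6, 25.4 and 6.7 per draw, so false calls against IgG exceeded the share that the adjustment aims at. Over the 933 noncoding entries the same shares were 35.4% and 92.9%, 34.1% and 93.3%, and 19.7% and 90.5%, with 20.6, 18.8 and 0.6 unchanged entries called. Sets of 30 genes changed 4-fold had an unadjusted camera p under 0.05 in 20 of 20 draws, and unchanged sets drawn from all genes in 0 of 20. Their mean differences from other genes were 1.51 to 1.56, and smaller differences were not tried. The list calls that follow are at an adjusted p under 0.05. Lists of short or sparsely read genes behaved differently, since camera called them without any group difference, in p400 and Ruvbl1 against IgG, in 18 and 18 of 20 draws for snoRNAs, 20 and 20 for microRNA precursors, 16 and 15 for box C/D RNAs, 11 and 12 for box H/ACA RNAs and 11 and 14 for histones. Ribosomal proteins and pluripotency factors were called in 0 of 20 in each comparison. Genes were simulated independently of each other, while the estimated correlation between members was 0.286 for ribosomal proteins and 0.527 for pluripotency factors. The simulated ranges are therefore too narrow for lists whose members vary together. The same simulation with no group difference gave the values printed beside the counts and lists. Since IgG serves both comparisons, it also gave the chance overlap and correlation of the 2.

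The alternative settings fixed then were pseudocounts of 0.1 and 5, no filter, a minimum mean of 2 RPKM, median centring, quantile normalization, every entry of the file, moderated variances with a trend and robust fitting, the 4 libraries of a comparison alone, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were IgG replicate 1 divided by the other table's total, voom on the recovered reads, all libraries thinned to the 99849 reads of IgG replicate 2, both of the first and last together, plus-strand entries alone, entries of at least 300 bases and 1 noncoding entry per symbol. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots drawn with matplotlib 3.10.9.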

Results

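The series asked which RNAs associate with the Tip60-p400 complex, a chromatin remodelling and histone acetyltransferase complex, in mouse embryonic stem cells. RNA was sequenced after immunoprecipitation (RIP-seq, in which a protein is precipitated with the RNA bound to it) from E14 embryonic stem cells of the Tip60-H3F genotype. The antibodies were IgG (the background control), one against Ruvbl1 and one against p400. Ruvbl1 is an AAA+ ATPase, and p400 (encoded by Ep400) is the remodelling ATPase of the complex. Each antibody had 2 libraries, 6 in all. Values were RPKM, reads scaled to the length of the gene span and to the library total, in a RefSeq gene table and a noncoding RNA table, both on the mm9 build.

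Depth differed 77.3-fold between libraries. The library totals recovered from the RefSeq table were 588724 and 99849 reads for IgG replicates 1 and 2, 2294343 and 2896709 for Ruvbl1, and 938466 and 7722302 for p400. In IgG replicate 2 a single read on 1 kilobase was worth 10.0 RPKM, against 0.129 RPKM in p400 replicate 2, so short genes with few reads were often at 0 in IgG. The noncoding table divided IgG replicate 1 by a total of 290700 reads, 2.03 times smaller than in the RefSeq table, and the other 5 libraries by the same total in both. With the larger total, IgG replicate 1 had 24.2% of its reads in RefSeq gene spans, against 39.9 to 42.8% in the other libraries. With the smaller total its 142536 reads there would be a share above that range, so the share does not settle which total is right. If the smaller total is right, the RefSeq fold changes against IgG given below are overstated. Genes on the plus strand took 94.4 to 96.9% of the RefSeq reads in every library. Actb, Gapdh, Eef1a1, Tubb5 and Rpl3, all abundant in these cells and all on the minus strand, were listed at 0 in all 6 libraries, so little can be said here of minus-strand genes. Of 12043 plus-strand symbols, 38.8% reached the minimum mean of 0.5 RPKM, against 2.89% of 11909 minus-strand symbols. Intervals and floors given below cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between libraries.

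**Figure D1:**
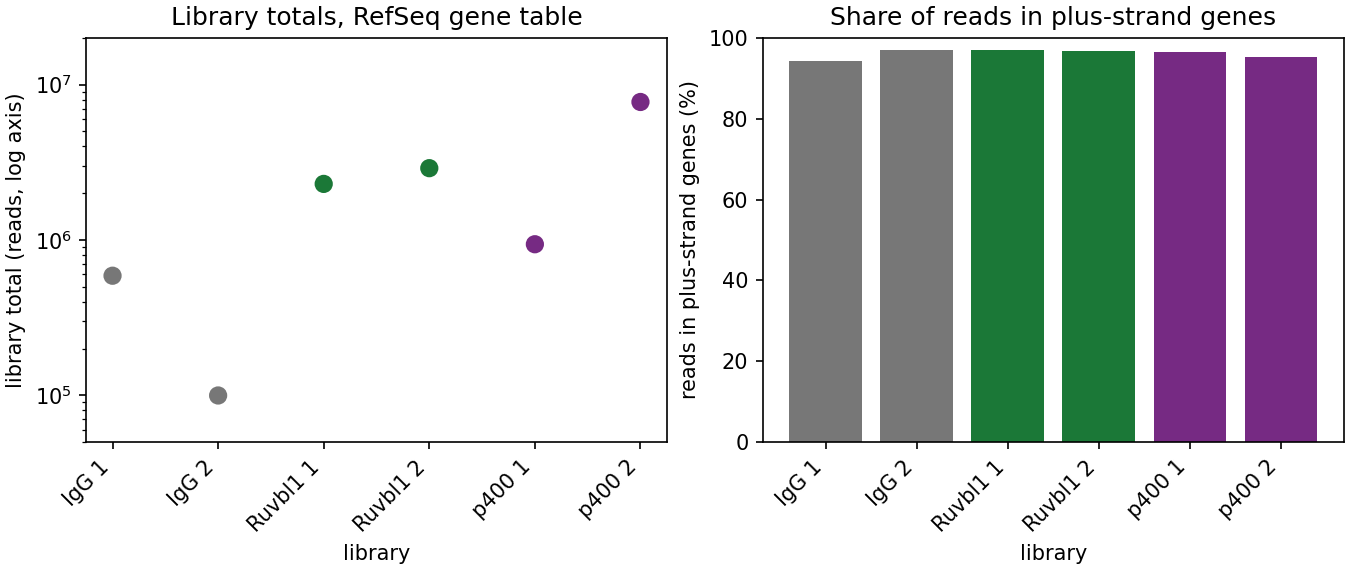
Library totals in reads (left, log axis) and the percentage of reads in plus-strand genes (right) for the 6 libraries of the RefSeq table, coloured by antibody. Totals ran from 99849 to 7722302 reads, and the plus-strand share from 94.4 to 96.9%.

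The RNAs of the precipitated proteins gave little information. Ruvbl1 RNA stood at 0.581 and 3.12 RPKM in the IgG libraries, 1.51 and 2.05 in the Ruvbl1 libraries and 1.23 and 1.36 in the p400 libraries. Its differences from IgG were within the spread between libraries (log2 fold change 0.12 ± 0.53 SE with Ruvbl1 and -0.16 ± 0.53 with p400, n = 2). Kat5, the gene of Tip60 on the minus strand, ranged from 0 to 0.877 RPKM, and Ep400, also on the minus strand, had 7 reads in p400 replicate 2 and at most 1 elsewhere. Xist, the X-inactivation RNA on the minus strand, read 4.83 and 7.45 RPKM with IgG, 7.59 and 10.5 with Ruvbl1 and 9.56 and 5.36 with p400. Tsix, its plus-strand antisense partner over the same locus, had log2 fold changes of 0.27 with Ruvbl1 and 0.16 with p400, and the 2 genes' reads cannot be told apart here. Xist was tested in each comparison and passed in none, either in the RefSeq table (log2 fold changes 0.22, 0.50 and -0.28) or as 2 transcripts of the noncoding table. Malat1 had 1 and 3 reads in 2 libraries, Neat1 1 and 7, and Kcnq1ot1 at most 7 in any library. Terc, Rmrp and Rpph1 were listed at 0 everywhere, and Rn7sk was not listed.

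The comparison of p400 with IgG asked which RNAs the p400 antibody enriched over background. The small nucleolar RNA Snord57, a box C/D guide RNA for ribosomal RNA methylation encoded in an intron of Nop56, was recovered with p400 and not with IgG. Snord57 (NR_028528; chromosome 2, 130103763 to 130103824) had 16 and 196 reads in the p400 libraries, or 275 and 409 RPKM, and none in either IgG library. This was at least 5.62-fold higher, counting 3 reads over both IgG libraries together, and at least 3.19-fold higher with the smaller total for IgG replicate 1. Its fitted log2 fold change was 8.39 ± 0.43 (SE, n = 2), with an adjusted p of 0.00473 by limma.

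Another 4 short RNAs without an IgG read passed the same test. They were the microRNA precursors Mir6904 (NR_105869, within the DNA repair gene Parp1, 5.32 ± 0.51), Mir5098 (NR_039557, within Rest, a repressor of neuronal genes, 4.94 ± 0.37) and Mir377 (NR_029878, within the imprinted noncoding RNA Mirg, 3.97 ± 0.39), and the box H/ACA RNA Snora30 (NR_034045, 4.42 ± 0.35; H/ACA RNAs guide pseudouridylation). Their adjusted p-values ran from 0.0210 to 0.0481 by limma. Each rested on 1 to 3 reads in p400 replicate 1 and 7 to 21 in replicate 2. Against 3 reads over the IgG libraries their p400 levels stood at ratios of 0.504, 0.610, 0.212 and 0.504, so a difference was not detectable at this depth. In all, 5 of 5022 genes tested passed upward and 0 downward by limma, with 260 upward and 13 downward at an unadjusted p under 0.05, while limma-voom on the recovered reads called 0 upward and 2 downward. Libraries simulated at the real totals with no group difference gave a mean of 11.4 calls and 216 upward at an unadjusted p under 0.05, so the number of calls did not exceed the simulation. Simulated levels of short entries can be too high, so this does not tell what few reads alone would give. Without IgG replicate 1 no gene passed upward and 2 passed downward, and leaving out any other library left 0 calls. With only the 4 libraries of this comparison 3 genes passed upward and 1 downward.

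**Figure D2:**
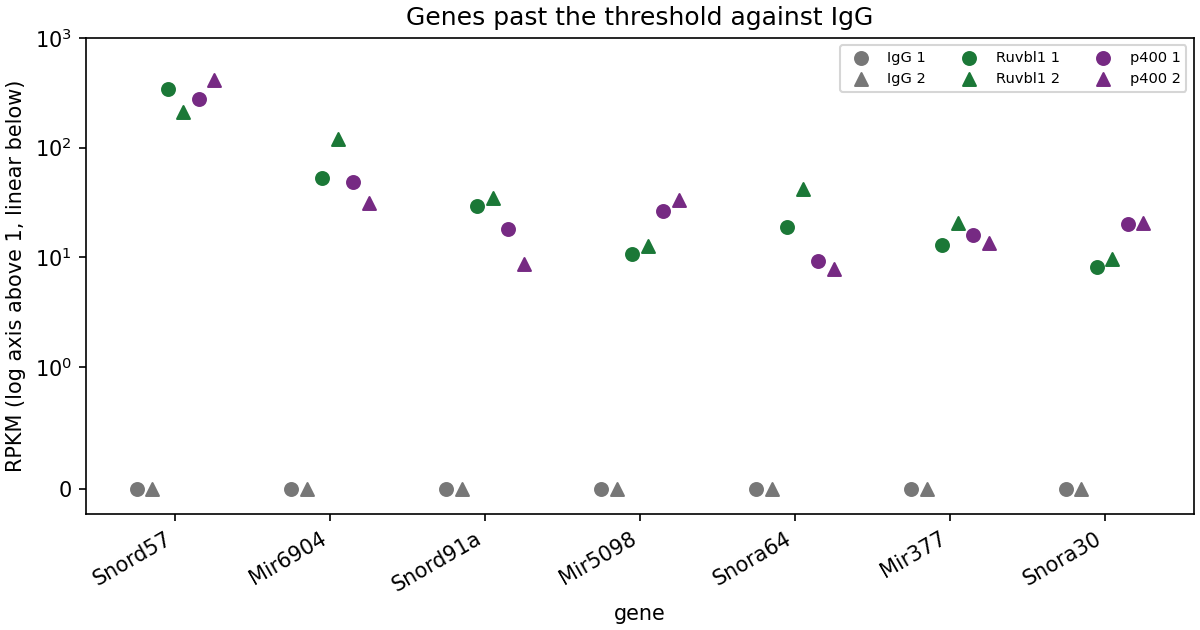
RPKM of the 7 RNAs past the threshold in p400 or Ruvbl1 against IgG, 1 point per library (circles replicate 1, triangles replicate 2; log axis above 1, linear below). Snord57 stood between 212 and 409 RPKM in the 4 antibody libraries, and all 7 RNAs were at 0 in both IgG libraries.

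No gene passed downward with p400 over all 6 libraries, and the genes nearest to it rested on few IgG reads. Polr2k, a small subunit shared by the RNA polymerases, had 3 and 1 reads with IgG and 1 and 2 with p400, a ratio of 0.0596 per read sequenced (95% counting interval 0.00873 to 0.352; adjusted p = 0.792 by limma). Gabarap, an autophagy protein gene, stood at 3.32 and 5.60 RPKM with IgG and 1.79 and 0.760 with p400 (-1.27 ± 0.43, adjusted p = 0.865 by limma). Alkbh7 (-1.47 ± 0.47), the minus-strand B430319G15Rik that overlaps Plod2 (-1.53 ± 0.45) and the precursor Mir1839 (2 and 1 reads with IgG, none with p400) did not pass either. Over all genes the median log2 fold change was 0.25. In both p400 libraries 23.9% of genes were higher and 2.15% lower than in both IgG libraries. Exchangeable libraries would give 16.7% each, and with unequal depths and an uncertain IgG total this is no measure of enrichment. The median moved with the scaling and became -0.01 with the smaller total for IgG replicate 1, where 166 of 259 genes at an unadjusted p under 0.05 were upward. With each library centred on its median the split was 126 upward of 195, after quantile normalization 128 of 236, under voom 192 of 309 and without IgG replicate 1 372 of 848.

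Among the gene lists fixed beforehand, small nucleolar RNAs rose against other genes with p400 (camera, difference in mean log2 fold change 0.89, adjusted p = 0.0499; adjusted p = 0.822 with an estimated correlation). Of their 43 measured members, 2 passed over all genes and 5 when adjusted over the list alone, and 28 had no IgG read. Box C/D RNAs passed (1.16, adjusted p = 0.0481; adjusted p = 0.822 with an estimated correlation), box H/ACA RNAs did not (0.51, adjusted p = 0.475), and neither did microRNA precursors (0.52, adjusted p = 0.170), of which 3 of 213 passed over all genes and 9 when adjusted over the list alone. The microRNA list passed upward under 9 of 21 alternatives, such as median centring (0.52, adjusted p = 0.00107) and leaving out IgG replicate 1 (0.84, adjusted p = 0.00299), and downward under 3, among them leaving out IgG replicate 2 (0.21, adjusted p = 0.000609). Snord91a (18.1 and 8.78 RPKM with p400) and Snora64 (9.19 and 7.81) had no IgG reads and missed the threshold. Simulation without a group difference gave the snoRNA list a mean difference of 1.01, more than that observed. Its call was lost without IgG replicate 2 (0.27, adjusted p = 0.0735) and without p400 replicate 2 (0.69, adjusted p = 0.812), and the call of box C/D RNAs was lost without the same libraries (0.81 and 0.74, adjusted p = 0.669 and 0.812).

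Genes of stem cell identity and of housekeeping functions did not pass as lists with p400. Cytoplasmic ribosomal proteins had 26 of 45 members above 0, where 70.0% of all genes were, and a difference from other genes of 0.02 (adjusted p = 0.707), while the test itself pointed down. Pluripotency factors differed by 0.10 (adjusted p = 0.707), where the test again pointed down, and their member Klf2 read 5.90 and 23.2 RPKM with IgG and 18.1 and 120 with p400 (1.90 ± 0.99). Immediate-early and stress genes differed by 0.71 (adjusted p = 0.414), with the stress response factor Ddit3 at 2.79 ± 0.90 and the growth-response factor Egr1 at 2.34 ± 1.07, the latter carried by p400 replicate 2 (636 reads against 4 in replicate 1). Differences were 0.30 for replication-dependent histones (10 of 25 without an IgG read), -0.29 for oxidative phosphorylation subunits, -0.07 for spliceosome and SR proteins, 0.04 for chromatin enzymes, -0.34 for cell cycle and replication genes, -0.11 for snoRNA host genes, -0.21 for nuclear-retained and imprinted long noncoding RNAs and -0.05 for Tip60-p400 complex subunits. None of these passed. Without p400 replicate 2 pluripotency factors differed by -0.55 and host genes by 0.49, and without p400 replicate 1 ribosomal proteins differed by -0.32. Oxidative phosphorylation subunits differed by -0.57 without p400 replicate 1 and by -0.43 without IgG replicate 2. That list passed downward by camera with every entry of the file (-0.33, adjusted p = 0.0212) and under voom (-0.56, adjusted p = 0.0196). The complex subunit Mrgbp read 1.96 and 0 RPKM with IgG and 9.84 and 5.41 with p400 (2.28 ± 0.61, adjusted p = 0.792 by limma).

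The comparison of Ruvbl1 with IgG asked the same of the Ruvbl1 antibody. Snord57 rose here too, with 49 and 38 reads (344 and 212 RPKM) against none in IgG, at least 3.85-fold higher than 3 reads over both IgG libraries and at least 2.18-fold with the smaller total (fitted log2 fold change 8.08 ± 0.43, n = 2, adjusted p = 0.00595 by limma). Mir6904 rose with 8 and 23 reads (52.8 and 120 RPKM), at least 1.37-fold on the same floor, or a ratio of 0.777 to it with the smaller total (6.34 ± 0.51, adjusted p = 0.0356 by limma). Snord91a, a C/D RNA within Tsr1 (5.05 ± 0.45), Snora64, an H/ACA RNA within the ribosomal protein gene Rps2 (4.86 ± 0.47), Mir377 (4.12 ± 0.39) and Mir5098 (3.67 ± 0.37) also passed, each at an adjusted p of 0.0406 by limma. Their 2 to 14 reads per library put them at ratios of 0.442, 0.840, 0.265 and 0.221 to 3 IgG reads, under what this depth could show.

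In all, 6 of 5022 genes passed upward with Ruvbl1 and 0 downward by limma, with 396 upward and 7 downward at an unadjusted p under 0.05, while limma-voom called 0 upward and 2 downward. Simulation without a group difference gave a mean of 11.7 calls and 226 upward at an unadjusted p under 0.05. The split was 254 upward of 314 with the smaller total for IgG replicate 1, 150 of 220 with each library centred on its median, 162 of 272 after quantile normalization, 198 of 240 under voom and 474 of 793 without IgG replicate 1. Without IgG replicate 1 there were 0 upward and 2 downward calls, and without any other single library, or with only the 4 libraries of this comparison, there were 0. The median log2 fold change was 0.39, or 0.12 with the smaller total for IgG replicate 1. In both Ruvbl1 libraries 37.6% of genes were higher and 2.23% lower than in both IgG libraries. Exchangeable libraries would give 16.7% each, which these are not, so the shares are no measure of enrichment. Consistent differences of at least 2-fold on the fitted scale in all 4 library pairs numbered 188 upward and 6 downward, against 107 and 3 with p400, and the simulation gave means of 84.5 and 72.3 upward. Over both antibodies, 295 upward and 9 downward became 806 and 738 without IgG replicate 1 and 126 and 31 with median centring. Downward, B430319G15Rik (-1.81 ± 0.45), Polr2k (-1.44 ± 0.41), Mir1839 (3 and 0 reads), Gabarap (-1.15 ± 0.43) and the X-linked ubiquitin hydrolase gene Usp51 (-1.26 ± 0.49) came nearest and did not pass.

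Small nucleolar RNAs rose as a list with Ruvbl1 (camera, 1.78, adjusted p = 2.0e-06; adjusted p = 0.199 with an estimated correlation), with 38 of 43 members above 0, where 79.3% of all genes were, 3 past the threshold over all genes and 13 when adjusted over the list alone. The difference was positive in 4 of 4 library pairs and exceeded the highest of 20 simulations without a group difference, 1.59, in which genes were drawn independently. Box C/D RNAs (2.22, adjusted p = 2.9e-06; adjusted p = 0.199 with an estimated correlation), box H/ACA RNAs (1.15, adjusted p = 0.0178; adjusted p = 0.515 with an estimated correlation) and microRNA precursors (0.93, adjusted p = 0.000381; adjusted p = 0.464 with an estimated correlation) passed as well. Adjusted over the list alone, 8 C/D RNAs, 5 H/ACA RNAs and 27 of 213 microRNA precursors passed, among the last Mir124a-1, a precursor of a neuronal microRNA (31.1 and 123 RPKM, 0 with IgG). The H/ACA and microRNA differences lay within or below what the simulation gave (means 1.04 and 1.23). Without IgG replicate 2 the snoRNA, C/D and H/ACA calls were lost (1.19, 1.93 and 0.19, adjusted p = 0.977, 0.433 and 0.391), and the H/ACA call also without Ruvbl1 replicate 2 (1.16, adjusted p = 0.0785). The snoRNA difference changed sign with libraries thinned to equal totals (-0.16), thinned with the smaller total for IgG replicate 1 (-0.11) and under voom (-1.59). Of the 43 members, 28 had no IgG read, and voom sets such entries by the read offset. Thinning left 22 members in a single drawing. These changes of sign therefore cannot decide whether the list rose. Without IgG replicate 2 the test of microRNA precursors passed downward (adjusted p = 0.0288), against a mean difference of 0.61. In summed reads the picture differed, since snoRNAs took 938 and 120 RPM (reads scaled to the library total alone) in IgG and 651 and 354 with Ruvbl1, most of them from Snord22 except in IgG replicate 2 (4 of 12 reads). Without Snord22, box C/D RNAs summed to a mean of 15.1 ± 6.96 RPM (SD, n = 2) with IgG, 45.7 ± 9.40 with Ruvbl1 and 35.5 ± 4.96 with p400, higher in all 4 library pairs for both antibodies, but on 6 and 2 IgG reads. All snoRNAs without Snord22 had means of 186 ± 150 RPM with IgG (292 and 80.1 in replicates 1 and 2), 153 ± 17.5 with Ruvbl1 and 156 ± 124 with p400, and box H/ACA RNAs 171 ± 157 (282 and 60.1), 108 ± 8.12 and 121 ± 129 RPM. Both sums went in different directions over the library pairs, with IgG replicate 1 highest.

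Ribosomal protein genes rose as a list with Ruvbl1 (0.50, adjusted p = 0.0178; adjusted p = 0.751 with an estimated correlation), with 39 of 45 above 0, where 79.3% of all genes were, and none past the threshold alone. Rps19, a small-subunit protein gene, read 5.01 and 5.91 RPKM with IgG and 33.8 and 22.5 with Ruvbl1 (2.15 ± 0.44), and the large-subunit genes Rpl28 (2.75 ± 0.60), Rpl18 (2.65 ± 0.62) and Rpl37a (2.60 ± 0.51) had the next smallest p-values. Their list summed to 1733 and 2874 RPM with IgG and 3778 and 2984 with Ruvbl1. With the smaller total IgG replicate 1 summed to 3509 and the call was lost (0.34, adjusted p = 0.0975), as it was without IgG replicate 1 (0.49, adjusted p = 0.152), Ruvbl1 replicate 1 (0.26, adjusted p = 0.306) or p400 replicate 1 (0.50, adjusted p = 0.0624). Introns of snoRNA host genes carry snoRNAs, whose reads also count for the host span. Among host genes, Gas5 read 39.8 and 35.7 RPKM with IgG and 317 and 133 with Ruvbl1 (2.41 ± 0.66, adjusted p = 0.437 by limma) and Snhg11 differed by 1.49 ± 0.38. Both passed when adjusted over the list alone, while the host list did not pass (0.64, adjusted p = 0.0666). It passed with a pseudocount of 5 (0.74), with median centring (0.64, adjusted p = 0.0379), after quantile normalization (0.84, adjusted p = 0.0213), with every entry of the file (0.66, adjusted p = 0.0434) and without Ruvbl1 replicate 2 (0.92, adjusted p = 0.0341).

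Pluripotency factors fell relative to other genes with Ruvbl1 (-0.38, adjusted p = 0.0497; adjusted p = 0.751 with an estimated correlation), with 9 of 17 above 0 (79.3% of all genes) against a median of 0.39 over other genes. Dppa4 (1.34 ± 0.46), Esrrb (0.52 ± 0.44), Klf2 (1.13 ± 0.99) and Pou5f1, which encodes Oct4 (-0.73 ± 0.64), were its members with the smallest p-values, and none passed. The call was lost without Ruvbl1 replicate 1 (-0.15, adjusted p = 0.306), and without IgG replicate 2 the difference changed sign (0.13, adjusted p = 0.876). With median centring the difference was the same and the call was lost (adjusted p = 0.143). No other list passed with Ruvbl1, the differences being 0.22 for complex subunits (Mrgbp 2.33 ± 0.61), 0.34 for histones (Hist1h2ai 2.28 ± 0.55), -0.25 for oxidative phosphorylation subunits (Ndufa11 1.35 ± 0.40), 0.01 for spliceosome and SR proteins (Prpf4b 1.32 ± 0.50), -0.02 for chromatin enzymes (Hdac2 1.21 ± 0.40), -0.17 for cell cycle genes (Pole 0.71 ± 0.47), 0.31 for immediate-early and stress genes (Hspa8 2.00 ± 0.85) and -0.26 for nuclear-retained and imprinted RNAs (Mirg 0.78 ± 0.45).

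**Figure D3:**
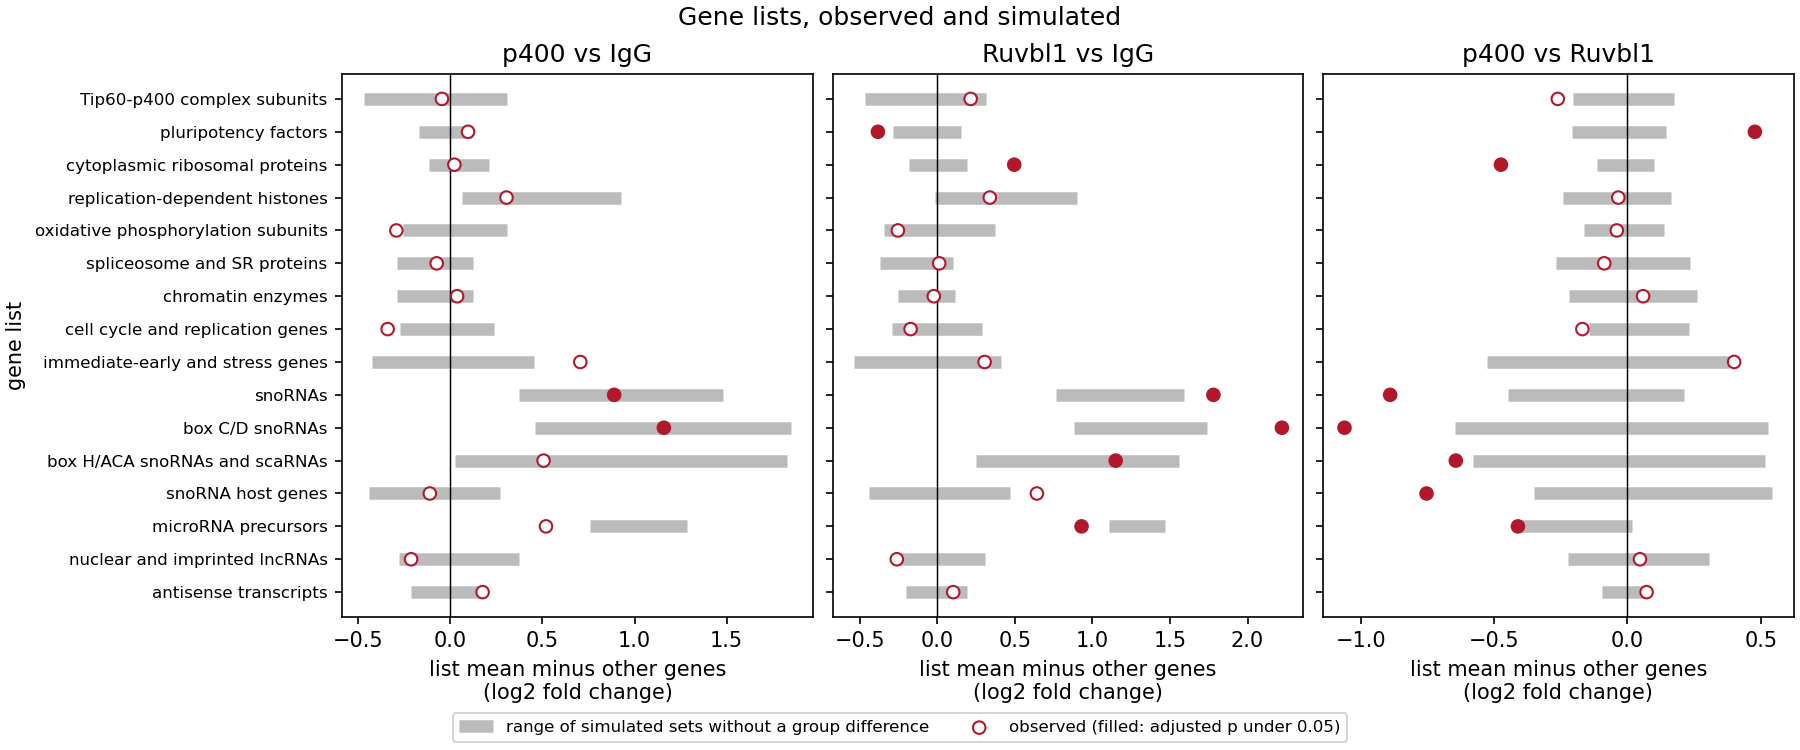
Difference between the mean log2 fold change of each gene list and that of the other genes in the 3 comparisons (points, filled where the adjusted p by camera was under 0.05), with the range of 20 simulations without a group difference (grey). The snoRNA lists lie right of 0 in the simulations against IgG, and ribosomal proteins lie outside the simulated range in Ruvbl1 against IgG and p400 against Ruvbl1. Genes were simulated independently, so the ranges are too narrow for lists whose members vary together. Lists that did not pass, such as cell cycle and replication genes in p400 against IgG, lie outside as well.

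The direct comparison of p400 with Ruvbl1 asked whether the antibodies brought down different RNAs. Ribosomal protein genes fell with p400 relative to Ruvbl1 as a list (camera, -0.48, adjusted p = 6.1e-06; adjusted p = 0.446 with an estimated correlation), with 43 of 45 members below 0, where 30.7% of all genes lay above 0. Rps19 read 33.8 and 22.5 RPKM with Ruvbl1 and 17.4 and 9.98 with p400 (-1.01 ± 0.44), and Rpl7a read 57.4 and 25.9 with Ruvbl1 against a mean of 12.6 with p400 (-1.55 ± 0.62). Rps16 (-1.09 ± 0.50) and Rpsa (-1.19 ± 0.57) lay the same way, and none passed alone. The list summed to 3778 and 2984 RPM with Ruvbl1 and 2865 and 1685 with p400. The difference was negative in 3 of 4 library pairs, and it was 0.09 for p400 replicate 1 against Ruvbl1 replicate 2. Without p400 replicate 2 the call was lost (-0.14, adjusted p = 0.251), as it was with all libraries thinned to equal totals (-0.50, adjusted p = 0.0913), and without Ruvbl1 replicate 1 or p400 replicate 1 the difference was -0.24 or -0.82.

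SnoRNA host genes fell with p400 relative to Ruvbl1 (-0.75, adjusted p = 0.00488; adjusted p = 0.446 with an estimated correlation), with 6 of 6 measured members below 0, again where 30.7% of all genes lay above. Gas5 read 317 and 133 RPKM with Ruvbl1 and 86.3 and 29.8 with p400 (-1.99 ± 0.66), 2410006H16Rik read 42.0 and 31.7 against 23.8 and 12.3 (-1.05 ± 0.45), and Snhg12 (-0.53 ± 0.39) and Snhg1 (-1.36 ± 1.13) followed. The host call was lost without Ruvbl1 replicate 1 (-0.47, adjusted p = 0.0581) or p400 replicate 2 (-0.15, adjusted p = 0.461). SnoRNAs fell too (-0.89, adjusted p = 0.000229; adjusted p = 0.390 with an estimated correlation), in 4 of 4 library pairs and below the lowest of the 20 simulations, -0.45. Gene spans include introns, so reads of snoRNAs inside host introns count for both lists. The host and snoRNA results are therefore not separate. Box C/D RNAs (-1.06, adjusted p = 0.000618; adjusted p = 0.390 with an estimated correlation), box H/ACA RNAs (-0.64, adjusted p = 0.0412; adjusted p = 0.446 with an estimated correlation) and microRNA precursors (-0.41, adjusted p = 0.00941; adjusted p = 0.446 with an estimated correlation) passed with them. The microRNA difference lay inside the simulated range (-0.42 to 0.02), and camera called that list in 4 of 20 simulations without a group difference, and host genes, snoRNAs and box C/D RNAs in 2 of 20 each. With libraries thinned to equal totals the snoRNA and H/ACA differences changed sign (0.22 and 0.43), over the 22 and 13 entries left in a single drawing. In summed reads the ratio of p400 to Ruvbl1 was 0.810 for snoRNAs, 1.02 for snoRNAs without Snord22, 0.724 for C/D and 1.12 for H/ACA RNAs, each mixed over the library pairs. For C/D RNAs without Snord22 it was 0.777, lower in all 4 pairs. Without p400 replicate 1 the snoRNA, C/D, H/ACA and microRNA calls were lost (-0.67, -0.61, -0.75 and -0.09, adjusted p = 0.318, 0.384, 0.346 and 0.318). Without IgG replicate 1 or 2 the H/ACA call (-0.65 in both, adjusted p = 0.225 and 0.199) and the microRNA call (-0.41 and -0.40, adjusted p = 0.477 and 0.456) were lost as well, and the H/ACA call was also lost without Ruvbl1 replicate 2 (-0.63, adjusted p = 0.317). Snora64 (-1.62 ± 0.47), Snord91a (-1.28 ± 0.45) and Snord49a (-2.99 ± 1.13) lay lower with p400 and Snora30 higher (1.10 ± 0.35), and 1 snoRNA, Snora3, passed downward when adjusted over the list alone.

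Pluripotency factors rose with p400 relative to Ruvbl1 (0.48, adjusted p = 0.0452; adjusted p = 0.757 with an estimated correlation), with 11 of 17 members above 0 (30.7% of all genes). Klf5 read 8.59 and 14.2 RPKM with Ruvbl1 and 8.54 and 96.8 with p400 (1.34 ± 1.21), Fgf4 read 25.5 and 24.9 against 30.4 and 43.2 (0.51 ± 0.45), and Tfcp2l1 (-0.65 ± 0.49) and Dnmt3l (-0.51 ± 0.48) lay the other way. Without p400 replicate 2 the difference changed sign (-0.17, adjusted p = 0.514), and the call was lost without IgG replicate 1, IgG replicate 2 or Ruvbl1 replicate 1 (0.47, 0.51 and 0.25, adjusted p = 0.0789, 0.0559 and 0.586). With median centring the difference was the same and the call was lost (adjusted p = 0.0940). Lists that did not pass were complex subunits (-0.26, H2afz -0.97 ± 0.58, with 9 of 9 below 0, where 30.7% of all genes lay above), histones (-0.03, Hist1h1a 0.80 ± 0.50), oxidative phosphorylation subunits (-0.04, Ndufv3 1.01 ± 0.50), spliceosome and SR proteins (-0.09, U2af2 -0.85 ± 0.64), chromatin enzymes (0.06, Ehmt2 -0.84 ± 0.55), cell cycle genes (-0.17, Cdc6 -0.28 ± 0.36), immediate-early and stress genes (0.40, Dnajb1 0.99 ± 1.31) and nuclear-retained and imprinted RNAs (0.05, Rian -0.77 ± 0.63). Without Ruvbl1 replicate 1 the differences of complex subunits and of spliceosome and SR proteins moved to -0.42 and -0.40.

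By limma 0 of 5022 genes passed between p400 and Ruvbl1, with 20 upward and 44 downward at an unadjusted p under 0.05, and voom also called 0, with 97 of 137 upward. The split was 31 upward of 63 with each library centred on its median, 48 of 94 after quantile normalization and 154 of 202 without p400 replicate 1. The smallest adjusted p was 0.393, shared by short RNAs on few reads. Mir1192, within Klf9, had 1 and 7 reads with p400 and none with Ruvbl1, and Mir494 had 4 and 2 reads with Ruvbl1 and none with p400. Mir1197 (3 and 2 reads), Mir6994 (1 and 3), Mir669m-1 (1 and 1) and Snora3 (1 and 2) were seen with Ruvbl1 alone. Mir5122 (1 and 3 reads) and Mir7080 (1 and 2) were seen with p400 alone. AA414768 (1.68 ± 0.38) and BC020402 (1.35 ± 0.36) came next upward and did not pass. Adjusted over the list alone, 2 microRNA precursors passed upward and 5 downward. Consistent 2-fold differences numbered 8 upward and 24 downward, and 7.53% and 23.9% of genes were higher or lower in all 4 pairs, where exchangeable libraries would give 16.7% each.

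**Figure D4:**
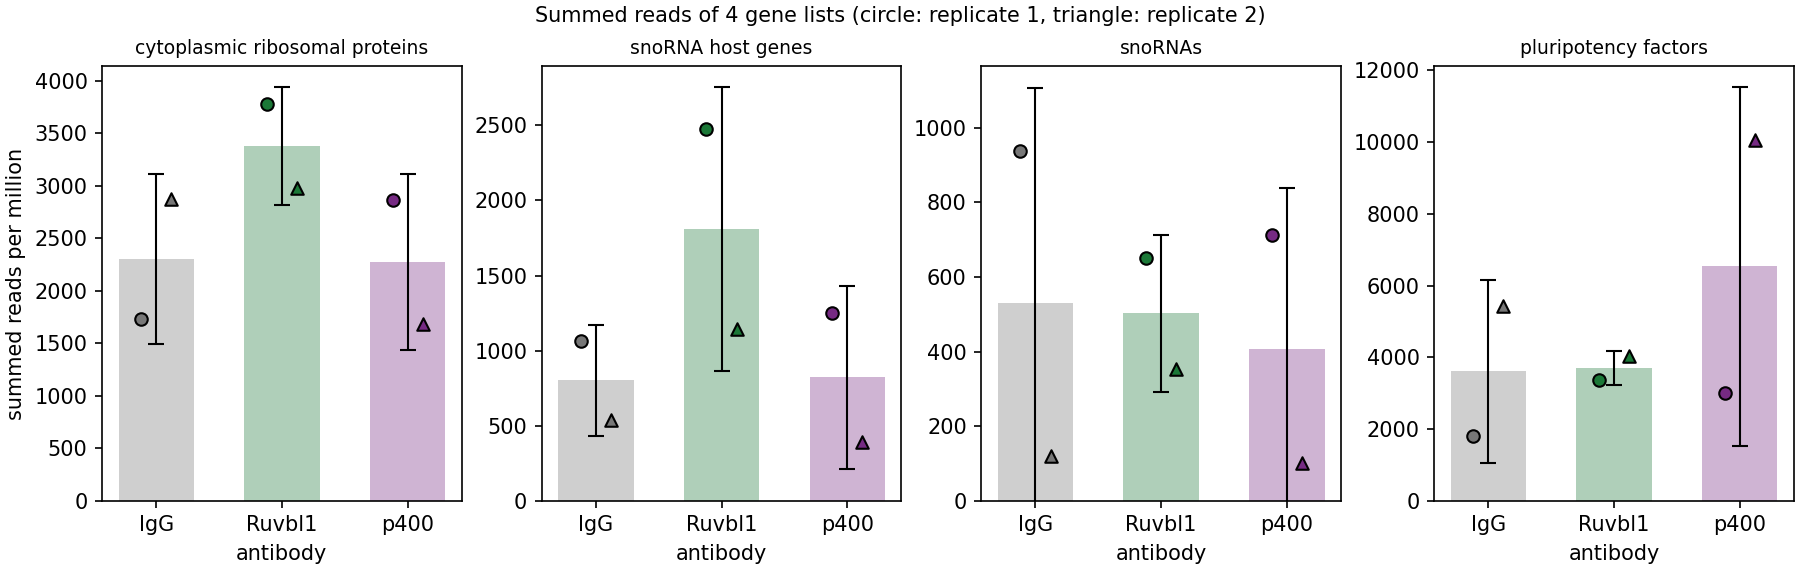
Summed RPM of 4 gene lists (bars, mean of 2 libraries; error bars, SD; circles replicate 1, triangles replicate 2). Ribosomal proteins summed to 3778 and 2984 RPM with Ruvbl1 and 2865 and 1685 with p400, and snoRNAs to 938 and 120 with IgG.

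Both antibody comparisons shared the IgG libraries. The 4 genes called in both, Snord57, Mir6904, Mir377 and Mir5098, stood beside a simulated mean of 8.5 shared calls with no effect at all, and beside 0.00597 for independent lists. Log2 fold changes correlated across genes at r = 0.72, against a mean of 0.76 in the simulation (0.74 to 0.77), and genes are not independent replicates. Their covariance was 0.361 against a simulated 0.346, a difference of 0.0156. Neither the shared calls nor the correlation exceeded the simulation, and the correlation lay below its range. Simulated levels of short entries can be too high, so this does not exclude a shared effect. The controls are only 2 libraries and could not be split, so the small excess in covariance may come from them. Across genes of the RefSeq table IgG replicate 1 correlated with IgG replicate 2 at r = 0.53, Ruvbl1 replicate 1 with replicate 2 at 0.79 and p400 replicate 1 with replicate 2 at 0.64. The highest correlation of each library there was with a same-numbered library of another antibody. It was 0.77 for IgG and p400 replicate 1, 0.83 for Ruvbl1 and p400 replicate 1, 0.81 for Ruvbl1 and p400 replicate 2 and 0.63 for IgG and Ruvbl1 replicate 2.

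In the noncoding table, 933 of 5894 entries were tested and 0 passed in any comparison by limma or by voom. At an unadjusted p under 0.05, 45 were upward and 12 downward with p400 against IgG, 62 and 4 with Ruvbl1 against IgG, and 3 and 15 with p400 against Ruvbl1. Against IgG the upward shares were 25 of 42 with p400 and 31 of 49 with Ruvbl1 after median centring, 4 of 94 and 4 of 63 under voom, and 74 of 151 and 121 of 192 without IgG replicate 1. With the RefSeq table's total for IgG replicate 1 they were 62 of 62 and 84 of 84, and between p400 and Ruvbl1 8 of 16 were upward after quantile normalization. The entry linc14940.1, an intergenic RNA on chromosome 17 (71183978 to 71185549), had 23 and 21 reads with Ruvbl1, 11 and 62 with p400 and none with IgG. It was at least 1.10-fold higher than 3 IgG reads with each antibody and did not pass (2.69 ± 0.44, adjusted p = 0.375 with Ruvbl1; 2.85 ± 0.44, adjusted p = 0.589 with p400, by limma). Gm13999 (2.26 ± 0.41 with Ruvbl1), which lies antisense to Mapkbp1, and Gm16069 (2.56 ± 0.48), antisense to Scamp3, also had no IgG reads. So did an entry over 0610005C13Rik antisense to Bcat2 (2.47 ± 0.44), Gm12569 (2.20 ± 0.44 with p400) and 1 transcript of 4933439C10Rik (2.35 ± 0.45 with Ruvbl1). Strand could not separate these antisense entries from the genes they overlap, since 384 of the 421 minus-strand entries tested overlap a plus-strand gene. Lowest against IgG were transcripts of Ankzf1 (-1.80 ± 0.46 with p400 and -1.16 ± 0.46 with Ruvbl1), entries over 2900076A07Rik (-2.08 ± 0.62 with p400) and entries over 1300002E11Rik (-1.36 ± 0.54 with Ruvbl1), and 1 unnamed entry on chromosome 1 (-1.42 ± 0.46 with Ruvbl1). Between p400 and Ruvbl1, Gas5 transcripts lay lowest (-2.24 ± 0.61 in the lowest) with 4933439C10Rik (-2.06 ± 0.45), and Gm12569 (1.93 ± 0.44), Gm13421 (1.09 ± 0.43) and Gm17041 (1.05 ± 0.46) highest. Antisense transcripts by symbol, a list of 61 measured entries, did not pass (0.17, 0.10 and 0.07 in the 3 comparisons).

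Markers of other cells that such a culture can hold could be read only in part, since 15 of 35 germ-layer and lineage regulators, 13 of 18 fibroblast markers and 11 of 18 primitive endoderm markers lie on the plus strand. Of germ-layer and lineage regulators only Eomes (0.134 to 10.1 RPKM) was measured, of fibroblast markers Thy1 (0 to 1.76) and Vim (0.399 to 4.70), and of primitive endoderm markers Lama1 and Lamb1 (0.502 to 3.64 and 0.535 to 1.93). These lists were too short to test, as was that of spliceosomal and other small nuclear RNAs with Rnu12, Vaultrc5 and Rprl2. None of these genes passed in a comparison. Mitochondrially encoded genes were not in the table.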

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

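The item below came from a rule set beforehand, and the comparisons with the other total and the RefSeq table were added after its value was seen. A Gas5 transcript of the noncoding table (ENSMUST00000161623.1) stood above both IgG libraries in both Ruvbl1 libraries and below both in both p400 libraries. It read 7.46 and 10.9 RPKM with IgG, 52.9 and 18.7 with Ruvbl1 and 6.36 and 5.48 with p400. The difference between the antibodies, tested directly, was a log2 fold change of -2.24 ± 0.61 (SE, n = 2) and did not pass (adjusted p = 1.00 by limma). With IgG replicate 1 divided by the other table's total its 7.46 became 3.68 RPKM, below both p400 libraries, so p400 no longer lay below both IgG libraries. The RefSeq entry of Gas5, whose IgG replicate 1 was divided by a total 2.03 times as large, read 39.8 and 35.7 RPKM with IgG and 86.3 and 29.8 with p400, which overlap.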

How the results depend on the processing

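Alternatives that rescale IgG replicate 1, use voom, thin the libraries, keep plus-strand entries or remove short ones were chosen after seeing the data. The count between p400 and Ruvbl1 stayed at 0 in both tables under all 22 alternatives, and the noncoding counts stayed at 0 except without a filter, where 11 entries passed with p400 (10 upward, 1 downward) and 1 with Ruvbl1, 1 of them shared. Calls for p400 and Ruvbl1 against IgG in the RefSeq table, 5 and 6 with 4 shared, became 17, 24 and 15 with a pseudocount of 0.1 and 3, 0 and 0 with a pseudocount of 5. They became 0, 0 and 0 without a filter, where 17034 genes were tested, 4, 3 and 2 at a minimum mean of 2 RPKM, 1, 1 and 1 with median centring, 3, 1 and 1 with quantile normalization, and 2, 12 and 1 with a trend and robust fitting. With only the 4 libraries of a comparison they were 4 (3 upward, 1 downward), 0 and 0. With each library left out in turn, a lone library being assumed to vary like the other groups, no call of the main fit was kept. With voom 2 and 2 genes passed, all downward, and whether these were the same genes was not counted. They were 0, 0 and 0 with thinned libraries, with thinned libraries and the other total, and without entries under 300 bases, which removes every gene called. The causes of the other shifts were not tested. With the other total, or on plus-strand entries alone, they were 6, 7 and 5.

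With the replicate number as a block, the 5 and 6 calls for p400 and Ruvbl1 with 4 shared became 2 and 1 with 1 shared. Box H/ACA RNAs no longer passed between p400 and Ruvbl1 (difference -0.64 in both fits, adjusted p = 0.0607), and snoRNA host genes passed with Ruvbl1 (0.64 in both, adjusted p = 0.0334). Deviations from replicate 1 to replicate 2 correlated across genes at 0.18 between IgG and Ruvbl1, 0.25 between IgG and p400 and 0.45 between Ruvbl1 and p400 (0.23, 0.36 and 0.50 in the noncoding table). The labels give the number no meaning and 2 pairs are too few to pair the samples by, so the other fits and the simulations did not use it. Their p-values and simulated ranges therefore leave out any effect that same-numbered libraries share.

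Of the 48 list tests, 15 passed (8 upward, 7 downward), and 0 with an estimated correlation. The split was 3 and 13 under voom, 1 and 9 without IgG replicate 2, and 8 and 1 with only the 4 libraries. The number was 5 without a filter, 9 with only the 4 libraries, 1 thinned, 0 thinned with the other total, and 3 without entries under 300 bases. Consistent 2-fold differences from IgG, 304 over both antibodies, were 864 and 74 with pseudocounts of 0.1 and 5, 187 at a minimum mean of 2 RPKM, 157 with median centring, 173 with quantile normalization, and between 461 and 1544 with a library left out. Upward and downward they were 295 and 9, against 806 and 738 without IgG replicate 1, 237 and 150 thinned with the other total, 126 and 31 with median centring and 128 and 45 with quantile normalization.

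For results past the threshold before or after, signs turned as follows, and for voom and thinning the short entries are set by the read offset or by few reads by construction. Under voom, Mir377 was -0.73 with p400 and -0.52 with Ruvbl1 and Mir5098 was -0.70 with Ruvbl1. Under voom, p400 against IgG gave histones -1.18, snoRNAs -2.11, C/D -2.14, H/ACA -2.05 and microRNA precursors -2.75, and Ruvbl1 against IgG gave -1.31, -1.59, -1.60, -1.57 and -2.57. Thinned, microRNA precursors were -0.59 with p400, snoRNAs -0.16 and H/ACA -0.43 with Ruvbl1, and 0.22 and 0.43 between p400 and Ruvbl1, and with the other total as well -0.11 and -0.43, and 0.22 and 0.43. Without IgG replicate 2, H/ACA with p400 was -0.45, pluripotency factors with Ruvbl1 0.13 and histones with Ruvbl1 -0.10, against 1.46, -0.88 and 0.75 without IgG replicate 1. Without p400 replicate 2, pluripotency factors between p400 and Ruvbl1 were -0.17, against 1.12 without p400 replicate 1. Another 84 list differences turned sign without passing, among them with p400 against IgG pluripotency factors (0.10, or -0.55 without p400 replicate 2), ribosomal proteins (0.02, or -0.32 without p400 replicate 1) and host genes (-0.11, or 0.49 without p400 replicate 2). Among 5248 results for single genes under alternatives, 4925 kept direction and side of the threshold, 146 no longer passed and 14 newly passed. List calls stayed past the threshold in their direction as follows. With p400 against IgG, snoRNAs and box C/D RNAs did in 11 of 21 alternatives each. With Ruvbl1 against IgG, snoRNAs and C/D did in 17 of 21 each, microRNA precursors in 16 of 21, H/ACA in 13 of 21, ribosomal proteins in 13 of 22 and pluripotency factors in 10 of 22. Between p400 and Ruvbl1, ribosomal proteins did in 19 of 22 (-0.82 to -0.14), host genes in 16 of 22, snoRNAs in 16 of 21, C/D in 15 of 21, microRNA precursors in 12 of 21, pluripotency factors in 9 of 22 and H/ACA in 8 of 21. Host genes with Ruvbl1 against IgG newly passed in 6 of 22, and microRNA precursors with p400 against IgG in 9 of 21 upward and 3 downward. Depth, 2 libraries per group and their spread together limit all of this. For p400 against IgG, 15.5% of simulated 4-fold and 88.0% of 16-fold changes were recovered.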

Other observations

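The 4 tests of snoRNAs and microRNAs, the thinning of ribosomal protein reads and the use of the other IgG total below were chosen only after the result was seen, and the other tests were written before theirs was seen. Some genes lay higher in replicate 2 of every group, and those named here were picked from them after their values were seen, so they stand for no gene group. Sox2, a core pluripotency factor, read 17.3 and 269 RPKM in IgG replicates 1 and 2, 38.5 and 171 in Ruvbl1 and 40.8 and 1839 in p400. Sox2ot, whose span holds Sox2 on the same strand, read 0.520 and 5.79, 1.06 and 4.49, and 1.16 and 42.1. Most of these reads can be those of Sox2, which had 25 and 66 reads in IgG where Sox2ot had 36 and 68. In p400 replicate 2 the numbers were 34867 and 38234, so Sox2ot is not a separate case. Zscan10, a zinc finger gene of pluripotent cells, read 1.84 and 24.6, 5.75 and 23.3, and 5.56 and 37.6. In all, 68 of 5022 genes lay at least 1 log2 unit higher in replicate 2 of every group, where independence would give 9.58, and 33 lay lower, where it would give 0.976. Of the 68, 37 had fewer than 10 reads in each IgG library. With the smaller total for IgG replicate 1, 55 of the 68 remained and 49 genes lay lower, where independence would give 5.21 and 2.36. Summed primitive endoderm markers read 603 and 201 RPM in Ruvbl1 replicates 1 and 2, 503 and 108 in p400 and 185 and 341 in IgG (375 and 341 with the smaller total). Fibroblast markers read 107 and 53.2, 121 and 39.0, and 42.5 and 100 RPM (86.0 and 100 in IgG with the smaller total). Pluripotency factors read 3374 and 4044, 2993 and 10068, and 1812 and 5418 RPM (3670 and 5418 in IgG with the smaller total). Without Sox2, the most abundant member, they read 3280 and 3623, 2893 and 5553, and 1770 and 4757 RPM.

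For these 68 genes, the share of the gene span that is exon was tested first. Their median share was 0.477 against 0.168 in other genes, a difference of 0.309 (permutation p = 0.0001, the smallest that 10000 permutations can give), and it was 0.314 without entries under 300 bases. Genes without an intron in their span, such as Sox2, Hexim1 and Zrsr1, were among them. Of the 63 genes of at least 300 bases, 14 (22.2%) had an exon share of at least 0.9, against 4.17% of other genes. Over all tested genes the rise in replicate 2 correlated weakly with exon share (Spearman rho 0.084 in IgG, 0.131 in Ruvbl1 and 0.265 in p400). The other genes were not matched on span or reads. More spliced RNA relative to intron RNA or DNA in replicate 2 is thus a possible explanation that this test cannot decide. GC content differed by 2.47 percentage points (permutation p = 0.0308), too little to decide. Depth ran opposite ways, with replicate 2 the shallower in IgG and the deeper in p400, and no biological explanation was tested, such as another mix of cells, since the labels do not say what a replicate is.

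The snoRNA list passed upward with both antibodies by camera (adjusted p = 0.822 with p400 and 0.199 with Ruvbl1 with an estimated correlation) and microRNA precursors with Ruvbl1 (0.464). Both lists turned sign under voom, where the read offset sets entries without an IgG read. Few reads in IgG could give this, since an entry of under 100 bases with no IgG read is set at 0 where a single read in IgG replicate 2 would be worth over 100 RPKM. Simulated libraries of the real totals without a group difference gave snoRNAs a mean difference of 1.01 with p400, where 0.89 was observed, and microRNA precursors 1.23 with Ruvbl1, where 0.93 was observed. For snoRNAs with Ruvbl1 they gave 1.17 on average and 1.59 at most against 1.78 observed. A read of IgG replicate 2 can set the simulated level of a short entry too high. These values therefore do not tell how much of the differences few reads account for. More snoRNA in the Ruvbl1 precipitates is the other explanation, and the ratio of mean summed snoRNA reads to IgG, 0.950, cannot be told apart from none given IgG libraries of 938 and 120 RPM, and it was 0.498 with the smaller total for IgG replicate 1.

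Ribosomal protein genes lay below other genes with p400 relative to Ruvbl1 (-0.48). The exon share of their spans was tested as the whole cause, and against 10000 lists matched on exon share and mean RPKM they still lay lower by a difference of -0.349, below all 10000, which argues against it. Unequal library totals were tested by thinning all libraries to the smallest, and the mean difference over 20 drawings was -0.538 (SD 0.128, none nearer to 0 than -0.33), which argues against them as the whole cause, although the call ended (adjusted p = 0.0913) as the median SE of the members went from 0.62 to 0.97. Membership of the 5' terminal oligopyrimidine class, RNAs translated under mTOR control, was the biological candidate, and of 29 other RNAs of this class fixed in a list, 16 were measured, 15 lay below 0 (30.7% of all genes lay above), and they differed from matched lists by -0.293 (percentile 1.34), among them Impdh2, Gnb2l1 and Eef2. The matched lists were drawn gene by gene and leave out correlation between members, so the percentiles are no significance levels, and no member passed alone. A property of the class stays a hypothesis only, since the ribosomal list call was lost without p400 replicate 2 (-0.14), so that 1 library decides it.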
